A study of Mus musculus with 2 samples.

How the data were processed

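H3K27ac chromatin immunoprecipitation sequencing was analysed from the processed peak lists of 2 biological replicates of embryonic day 16.5 mouse intestine, which form 1 group. Per the text descriptions that came with the files, 1 list was called on each replicate, 1 on both replicates together (the pooled list), and 1 is a replicated list derived from the peak lists of replicate 1, replicate 2 and the pool. Per the same descriptions, the peaks of each replicate were derived from its filtered alignments and further input files, more for replicate 1 than for replicate 2, in the mm10 build. The aligner, the peak caller, their versions and the rule of the replication step were not given in the sources used here. Because the replicated list draws on all other lists, it is not independent of either replicate.

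Each list has 1 line per peak. The deposited peak score is a value scaled by the authors within a list and was not used. The enrichment per peak is the deposited signal value, a ratio whose reference is not given for the peak files, and it was used to rank, filter and describe peaks within a list. The −log10 p and −log10 q values are those deposited by the authors; the −log10 q served as a filter in an alternative, and the −log10 p was not used. In the replicated list 0.509% of peaks had a q above 0.05, in replicate 1 5.01% and in replicate 2 7.55%. The deposited summit offset placed the motif windows. The number of reads is not in the lists, so the depth is unknown, and differences between the lists of the 2 replicates can reflect depth and calling as well as tissue. Intervals are exact binomial 95% intervals over peaks or genes and cover counting only.

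Peaks on chromosomes 1 to 19, X and Y were used. Chromosome lengths of the mm10 reference were compared with the peak positions, and no peak ended past a chromosome. Genes came from GENCODE release M21: 21938 protein-coding genes, with every annotated transcript start as a TSS. A promoter peak is a peak that overlaps the 1 kb on either side of a TSS by at least 1 bp, and a distal peak lies farther from every TSS. The promoter enrichment of a gene is the highest among the promoter peaks at any of its annotated starts, which can lie inside the gene. Coordinates are 1-based. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Overlaps had been intended for bedtools; they were computed with interval code written for this work, which gave the same results as bedtools 2.31.1 on simulated data.

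Replicate lists were compared by overlap of at least 1 bp and by the Jaccard index, against 100 shuffles of peaks within chromosomes. Before the data were examined, 25 gene lists (cell types of the gut, other organs, signalling, cell cycle, housekeeping and Hox genes), the tests, the alternatives and the rule for naming genes were fixed. Of the listed genes, Ahsp, Amy2b and Cblif were not in the annotation under these symbols. Ascl2 and Sox9 stand in both the transcription factor and the stem and progenitor list. The share of a list's genes with a promoter peak was tested with Fisher's exact test against all other protein-coding genes. The median bases covered within 10 kb and the median number of distal peaks within 50 kb of the TSS, taken as the 5′ end of the gene, were set against 10000 random lists of the same size matched on the number of protein-coding TSSs within 50 kb, in 5 bins, which amounts to a permutation of list membership within bins. All tests were two-sided and adjusted by Benjamini-Hochberg over the 25 lists of a measure, with a threshold of 0.05. In 1 alternative the random lists were matched on the CpG observed/expected ratio of the promoter, in 10 bins.

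Peaks at most 12.5 kb apart were stitched into domains and ranked by covered bases. Motif matches of 11 consensus sequences on either strand were sought in 500 bp around distal summits and in windows of the same chromosome matched on GC content in bins of 2%, with 20 draws, and compared with 20 column-permuted strings per motif. Motifs near the epithelial lists and near the mesenchyme and smooth muscle lists were compared by Fisher's exact test; peaks near both (13) were left out.

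Named were, for each list, up to 3 members with the highest promoter enrichment and up to 3 without a promoter peak in any list, in alphabetical order; the 10 genes and 10 distal peaks with the highest enrichment; the 10 domains with most covered bases; and 5 genes per replicate with a promoter peak there alone. Genes named as exceptions to a count (Lgr5, Olfm4, Vdr, Hoxc8 and Hoxd11, and the remaining Hox genes), the list members in the leading domains and the non-coding genes in them were chosen after their values were seen.

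The tests were run on simulated lists. By Fisher's exact test, 5.16% of 5000 unchanged lists of 22 genes passed an unadjusted p of 0.05, and 100% of 200 raised lists were found; the first 500 unchanged lists had given 8.00%, which reached the limit set for this check, and their number was then raised with the same seed. With random lists, 0.6% of 500 unchanged lists of 20 genes and 82.5% of 200 raised lists passed the same p, so that test was conservative for the simulated counts. These counts were drawn independently for each gene, whereas neighbouring genes share real distal peaks. The simulation therefore does not show that the test is conservative for the real distal counts. Alternatives covered the overlap that counts as shared, stricter enrichment and q thresholds, window sizes, the pooled list, each replicate left out, the TSS definition, the matching of random lists and the stitching gap.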

Results

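H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the intestine of B6NCrl mouse embryos at embryonic day 16.5. The samples form 1 group of 2 biological replicates, each pooled from male and female embryos. Replicate 2 was pooled from 41 embryos, and the labels give no number for replicate 1. There was no second condition, so the comparisons are between gene groups, genomic regions and the 2 replicates. The measurements are peak lists in the mm10 build: 103571 peaks in replicate 1, 90611 in replicate 2, 96837 in the pooled list and 64834 in the replicated list, counted on the main chromosomes. The replicated peaks had a median width of 513 bp and covered 47.7 Mb, 1.80% of the genome. The number of reads behind each list is unknown. The enrichment printed for a peak is the authors' own value and is used here to rank, filter and describe peaks within a list.

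Promoters of genes that build the intestinal epithelium, its mesenchyme and its smooth muscle carried H3K27ac peaks far more often than other genes. Promoters of endocrine cells and of other organs carried them less often, but for several organs this call ended against lists matched on promoter CpG. Of 21938 protein-coding genes, 12289 (56.0%) had a replicated peak within 1 kb of a transcription start site (TSS), and the median promoter enrichment was 9.83. All 24 smooth muscle genes and all 25 genes of epithelial structure and adhesion had a promoter peak (adjusted exact p = 8.23e-06 for each, Fisher's exact test). So did 23 of the 24 intestinal epithelial transcription factors (95.8%, adjusted exact p = 9.33e-05) and 27 of the 30 mesenchyme and fibroblast genes (90.0%, adjusted exact p = 0.000281). Neither of 2 widely used adult stem cell markers, Lgr5 and Olfm4, had a replicated promoter peak, although 18 of the 20 stem and progenitor genes did (90.0%, adjusted exact p = 0.00422). These 2 genes had promoter peaks in replicate 1 alone, with enrichments of 2.51 and 3.45, and are named as the exceptions, after their values were seen.

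Among the epithelial transcription factors the highest promoter enrichments were at Gata6 (22.4), Hnf1a (18.2) and Hnf4a (15.9), regulators of endodermal and intestinal gene expression. The Hnf4a peak lay inside the gene, on chromosome 2 from 163550869 to 163552625, with the 5′ end at 163506808. The Gata6 peak spanned 7094 bp on chromosome 18 from 11049162 to 11056255, across the start of the gene. The exception, likewise chosen after its values were seen, was Vdr, the vitamin D receptor gene, which had a promoter peak in replicate 1 alone. Of the structural genes, Ezr, which encodes the microvillus linker ezrin, reached 22.96, the tight junction gene Cldn7 20.5 and the adhesion gene Epcam 20.4. The Epcam peak lay on chromosome 17 from 87635000 to 87636592. Among the stem and progenitor genes, the Wnt feedback gene Axin2 had a promoter enrichment of 35.1, the receptor gene Lgr4 23.6 and Myc 21.6.

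Mesenchymal promoters were led by the nuclear receptor gene Nr2f2 (29.9), the homeobox gene Meis1 (23.8) and the intermediate filament gene Vim (18.5). The Nr2f2 peak lay inside the gene, on chromosome 7 from 70358146 to 70361806, with the 5′ end at 70366735. The 3 mesenchymal genes without a promoter peak in any list were Barx1, a regulator of stomach mesenchyme, Fbln2 and Thy1. In smooth muscle the contractile genes Myl6, Tpm1 and Smtn had enrichments of 20.9, 17.0 and 15.3. Those of Tpm1 and Smtn came from peaks inside the genes, counted through internal annotated starts. For Tpm1 the peak ran from 67038818 to 67044348 on chromosome 9, with the 5′ end at 67049406. For Smtn it ran from 3535222 to 3537113 on chromosome 11, with the 5′ end at 3540612. Hedgehog and BMP signalling genes had promoter peaks at 23 of 24 members (95.8%, adjusted exact p = 9.33e-05), with Smad7 at 33.9, Id2 at 24.7 and the hedgehog receptor gene Ptch1 at 23.8. The exception, the BMP antagonist gene Grem2, had none in any list. Wnt, Notch and FGF genes had them at 22 of 27 members (81.5%, adjusted exact p = 0.0142), with Fgfr2 at 31.6, Tcf7l2 at 27.2 and Hes1 at 27.1. Hes5, Lef1 and Rspo2 had no promoter peak in any list. All 21 cell cycle genes (adjusted exact p = 3.77e-05) and all 20 housekeeping genes (adjusted exact p = 4.63e-05) had promoter peaks, among them Birc5 (24.5), Tk1 (22.6) and Actb (46.5).

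Enterocyte genes were split. A promoter peak was present at 22 of 30 (73.3%, adjusted exact p = 0.0802), which did not pass the threshold. Mttp, which is needed to assemble lipoproteins, had an enrichment of 30.3, the apolipoprotein gene Apoc3 13.3 and the peptidase gene Dpp4 12.7. Aqp8, Car1 and Cyp3a11 had no promoter peak in any list. Goblet, Paneth and tuft cell genes had peaks at 7 of 20 (adjusted exact p = 0.0810), led by Creb3l1 at 7.20, and the goblet gene Clca1, the lectin gene Itln1 and the Paneth gene Lyz1 had none. Enteroendocrine genes were lower at 2 of 22 (9.09%, adjusted exact p = 4.28e-05). These 2 were Sct, the secretin gene (14.6), and Insm1 (4.06), while Arx, Cck and Chga had no promoter peak in any list. The Sct peak, on chromosome 7 from 141275483 to 141278208, lay wholly past the 3′ end of the gene at 141278330. It was counted because it reached into the 1 kb window. Insm1 had no promoter peak in replicate 2's own list.

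Of the remaining cell types of the gut wall, enteric neurons and glia had promoter peaks at 9 of 25 genes (adjusted exact p = 0.0802), but at 60% in replicate 1's own list and 56% in replicate 2's, close to the 59.3% and 56.9% of other genes (adjusted p = 1 for both). Erbb3 (17.0), Hand2 (9.59) and Ednrb (9.39), which act in neural crest development, led this group, and the neuronal enzyme genes Chat and Nos1 had none. Endothelial genes had peaks at 14 of 20, led by Eng at 15.4 (at 40% with an enrichment of at least 4, below other genes). The Eng peak lay inside the gene, on chromosome 2 from 32672006 to 32673695, with the 5′ end at 32646595. Interstitial cells of Cajal with mesothelium had them at 5 of 13 (38.5%), led by Etv1 at 13.8. Neither of these 2 lists passed the threshold. Immune genes were lower at 7 of 22 (31.8%, adjusted exact p = 0.0393), with the highest enrichment, 4.08, at Lck, and no peak at Cd19 or Cd3e. Erythroid genes were lower at 3 of 15 (adjusted exact p = 0.0105): Tfrc (15.3), Klf1 (9.83) and Nfe2 (4.98).

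Marker genes of other organs had promoter peaks less often than other genes. Against random lists matched on promoter CpG, only the stomach, brain and germ line calls among these lists remained. None of 17 stomach genes had a replicated promoter peak (adjusted exact p = 8.23e-06), including the acid pump genes Atp4a and Atp4b. Liver genes had them at 5 of 22 (22.7%, adjusted exact p = 0.00422), among them Apoh (11.9), Ttr (8.44) and Hhex (6.69), and at 40.9% in replicate 1's own list, while Alb and Ahsg had none in any list. Pancreas genes had them at 4 of 19 (21.1%, adjusted exact p = 0.00422), among them Cela1 (7.42) and Pdx1 (4.53). Heart and skeletal muscle genes had them at 5 of 20 (adjusted exact p = 0.00963), led by Mylpf at 9.98, and Acta1, Actc1 and Ckm had none. Brain genes had them at 3 of 22 (13.6%, adjusted exact p = 0.000133): Satb2 (12.502), Dlx2 (4.64) and Dlx1 (4.19). Lung and kidney genes had them at 5 of 21 (23.8%, adjusted exact p = 0.00593), led by Pax8 at 7.25, and germ line genes at 2 of 20 (adjusted exact p = 9.33e-05), Gdf9 (9.47) and Dazl (6.01).

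In all, 9 of the 25 fixed lists were called higher and 10 lower after Benjamini-Hochberg adjustment of the two-sided tests over the lists; genes are not independent replicates, so each p describes these peak lists only. Against random lists matched on the CpG content of the promoter, the calls for stem and progenitor, Wnt, Notch and FGF, immune, erythroid, liver, pancreas, heart and skeletal muscle, and lung and kidney genes ended, the immune share turned to above its matched background, and the enterocyte list was called higher. In replicate 1's own list the calls for immune, liver, and heart and skeletal muscle genes ended, with the pooled list these and the pancreas call, and with a 2.5 kb window the pancreas and the heart and skeletal muscle calls. The Wnt, Notch and FGF call ended with peaks of an enrichment of at least 4 and with the 5′ end of the gene as its only TSS. Goblet, Paneth and tuft genes were called lower with an enrichment of at least 4, and enteric neurons and glia with that threshold and with the summit inside the window.

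**Figure D1:**
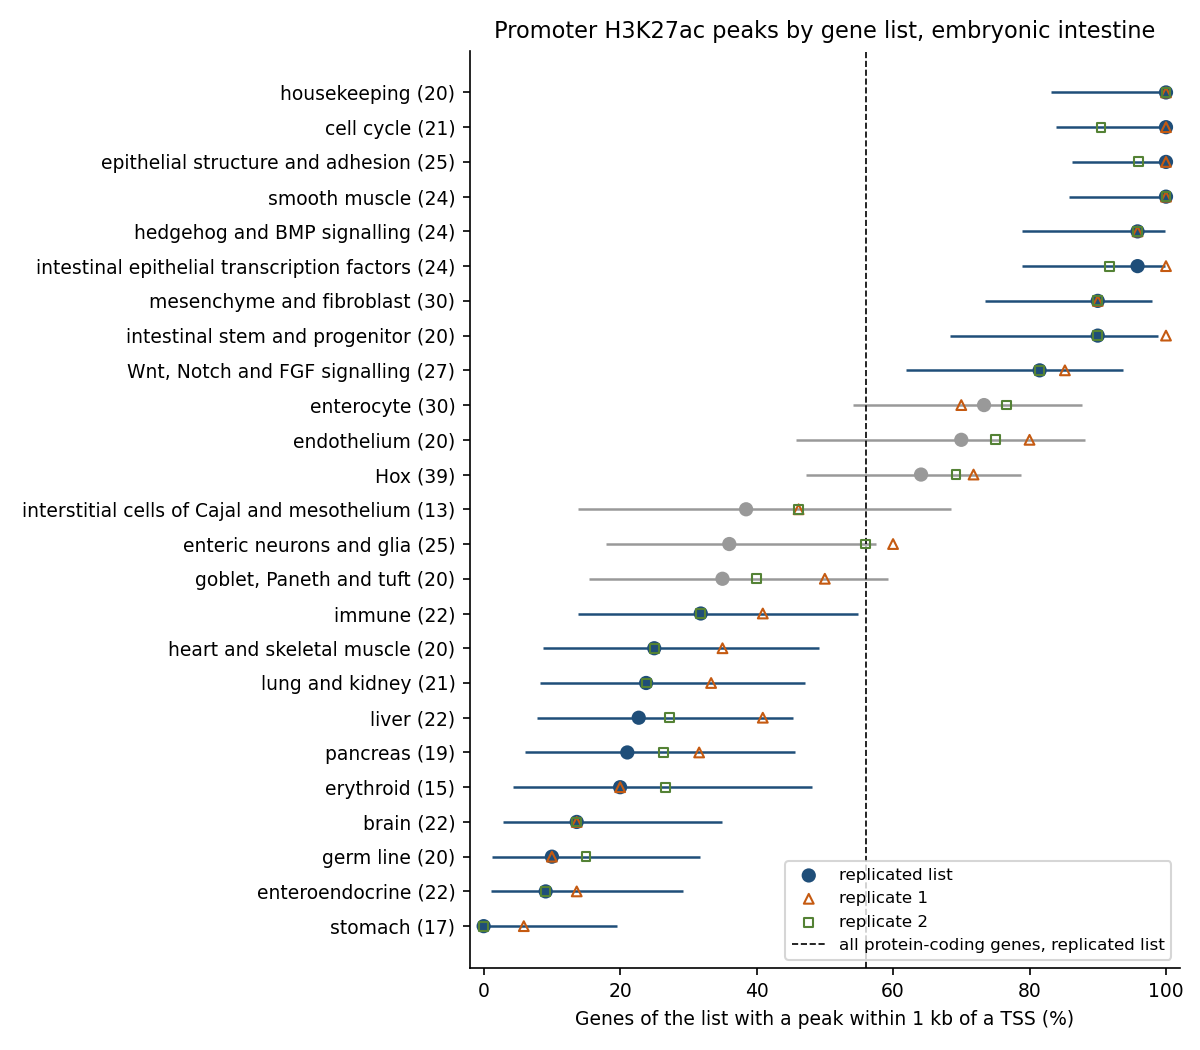
Percent of the genes of each fixed list (number of genes in brackets) with an H3K27ac peak within 1 kb of a TSS. Filled circles give the replicated list with the exact 95% binomial interval, blue where the list was called and grey where it was not; triangles and squares give replicates 1 and 2, and the dashed line marks the 56.0% of all protein-coding genes.

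Among all genes, the highest promoter enrichment in the replicated list was 52.7 at Sp3, a transcription factor gene. It was followed by the histone gene Hist4h4 (51.3) and by Erbin and Zfp143 (49.8 each). Gpr19 (49.7), Arid1a (49.1), Etv6 (47.9), Arrdc3 (47.0), Actb (46.5) and N4bp2 (46.0) completed the leading 10. The Sp3 peak spanned 2870 bp on chromosome 2 from 72978437 to 72981306 and had 46.4 in replicate 1 and 47.3 in replicate 2. Both replicates had a promoter peak at 12119 genes, replicate 1 alone at 893 and replicate 2 alone at 357. The genes with the highest enrichment in replicate 1 alone were Gm10647 (14.7), Ell2, Has2 and Rtkn2 (6.89 each) and Mroh5 (6.69). In replicate 2 alone they were Ppp1r27 (22.4), Apoe (9.13), Abca17 (7.52), Lrrc4 (7.44) and Slc2a2 (5.65). These differences concern the 1 kb window in the replicates' own lists only. Within 10 kb of the TSS replicate 1 covered more bases than replicate 2 at Ppp1r27 (3632 against 3302 bp), Apoe (4477 against 4162 bp) and Slc2a2 (2939 against 2533 bp), and fewer at Abca17 (723 against 876 bp) and Lrrc4 (1252 against 1860 bp). Replicate 2 covered 741 bp there at Gm10647, 744 bp at Has2 and none at Ell2, Rtkn2 and Mroh5.

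Peaks also covered more bases around genes of epithelial structure, epithelial transcription factors, enterocytes, mesenchyme and smooth muscle. Promoter peaks count among these bases and the random lists were not matched on them, so the medians partly restate the promoter shares. Within 10 kb of the TSS, replicated peaks covered a median of 5765 bp at genes of epithelial structure, against 779 bp in random lists matched on gene density. Epithelial transcription factors had 4356 bp against 569 bp, mesenchymal genes 4164 bp against 527 bp, smooth muscle genes 3337.5 bp against 731 bp, and hedgehog and BMP genes 3455 bp against 563 bp. Housekeeping genes had 4865.5 bp against 951.5 bp and Hox genes 3612 bp against 1370 bp. Each of these 7 lists lay above all 10000 random lists (adjusted permutation p = 0.000714). Their unadjusted p of 0.0002 is the smallest the random lists can give. Stem and progenitor genes had 2666.5 bp against 507 bp and Wnt, Notch and FGF genes 2252 bp against 454 bp (adjusted permutation p = 0.00111 for both). Cell cycle genes had 2441 bp against 863 bp (adjusted permutation p = 0.0125) and enterocyte genes 1582.5 bp against 569.5 bp (adjusted permutation p = 0.0255). Goblet, Paneth and tuft genes had 220 bp against 592.75 bp and were not called. The lists of the other organs, the blood lists and the enteroendocrine list had medians of 0 to 253.5 bp. A median of 0 is the lowest possible and was also reached by random lists, so lists there could not be called lower. Hox genes lie in 4 clusters and share peaks, so the p against scattered random genes is too small for them; against random runs of neighbouring genes, an alternative chosen after seeing the data, the Hox call ended (adjusted permutation p = 0.115). It also ended with a 5 kb window, the cell cycle call with a 25 kb window, the Hox and enterocyte calls with peaks of an enrichment of at least 4, and the enterocyte call with unmatched random lists.

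Distal peaks, over 1 kb from any TSS, were also more frequent around genes of epithelial structure, epithelial transcription factors, enterocytes, mesenchyme and smooth muscle. Goblet, Paneth and tuft genes had a median of 1 within 50 kb, as in matched random lists. Within 50 kb of the TSS, genes of epithelial structure had a median of 11 distal peaks, against 1 in matched random lists. Ezr had 19 such peaks, Epcam 12 and Cldn7 5. Hox genes had 8 against 2, epithelial transcription factors 7 against 1, enterocyte genes 6 against 1 and smooth muscle genes 5.5 against 1. For these 4 lists and epithelial structure the adjusted permutation p was 0.001. Their unadjusted p of 0.0002 is the smallest the random lists can give. Against random runs of neighbouring genes, which allow for the peaks that clustered Hox genes share, the Hox median was 8 against 2 (adjusted permutation p = 0.0160). Dpp4 had 13 distal peaks, Apoc3 11 and Tpm1 17. Hedgehog and BMP genes had 5 and mesenchymal genes 4 (adjusted permutation p = 0.00357 for both), Wnt, Notch and FGF genes 4 (adjusted permutation p = 0.00937), endothelial genes 4.5 (adjusted permutation p = 0.0122), cell cycle genes 5 (adjusted permutation p = 0.0135), and stem and progenitor genes 3.5 (adjusted permutation p = 0.0359). Housekeeping genes had 3.5 against 1.5 and were not called (adjusted permutation p = 0.171), close to the mesenchymal and stem medians. The random lists were not matched on promoter peaks, so the calls do not compare these genes with others that have a promoter peak. The enteroendocrine, erythroid, brain, and lung and kidney lists had a median of 0, at which a list could not be called lower. In the own, longer lists of replicates 1 and 2 the medians were higher, mostly in random lists too: 14 and 17 at genes of epithelial structure (2 in random lists in both), 16 and 12 at Hox genes (4 and 3), 12 and 10.5 at epithelial transcription factors (2 and 1), 10 and 8.5 at smooth muscle genes (2 in both) and 7 and 8.5 at enterocyte genes (2 and 1). Mesenchymal genes had 7 in both (2 and 1 in random lists), Wnt, Notch and FGF genes 8 and 6 (2 and 1), and stem and progenitor genes 6 and 4 (1.5 and 1), and of these 8 calls only that of the stem and progenitor genes ended, in replicate 2's list. With a 20 kb window the stem, endothelial, Wnt and Hox calls ended and housekeeping genes were called higher, with a 100 kb window the endothelial and cell cycle calls ended, and with unmatched random lists the stem call ended. The endothelial, cell cycle and stem calls ended with peaks of an enrichment of at least 4 and with at least 1 replicate's own list; for these 3 lists the highest adjusted p values over all alternatives were 0.328, 0.456 and 0.229.

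Along the Hox clusters, which specify position along the body axis, the peaks covered larger shares of the Hoxa and Hoxb clusters than of Hoxc and Hoxd, a comparison without a test. Replicated peaks covered 45.2% of Hoxa on chromosome 6 and 33.8% of Hoxb on chromosome 11, against 13.2% of Hoxc on chromosome 15 and 8.53% of Hoxd on chromosome 2. The shares in replicates 1 and 2 were 42.3% and 39.5% for Hoxa, 33.9% and 31.7% for Hoxb, 14.1% and 12.0% for Hoxc, and 10.9% and 7.83% for Hoxd. Of the 39 Hox genes, 25 had a replicated promoter peak (64.1%), a share that was not called: 10 of 11 in Hoxa, 8 of 10 in Hoxb, 3 of 9 in Hoxc and 4 of 9 in Hoxd. Promoter peaks were present at 10 of 12 genes of paralogue groups 1 to 4, at 10 of 11 of groups 5 to 8 and at 5 of 16 of groups 9 to 13. Hoxa13, Hoxb13, Hoxc13 and Hoxd13, the genes of the most posterior group, had no promoter peak in any list, and neither did Hoxb1 and Hoxd1. The highest promoter enrichments were at Hoxb2 (19.7), Hoxb4 (18.3) and Hoxb3 (15.5). Hoxc8 and Hoxd11, chosen after their values were seen, had promoter peaks in both replicates but not in the replicated list. With peaks of an enrichment of at least 4, the bases covered in Hoxd fell from 8256 to 3965.

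**Figure D2:**
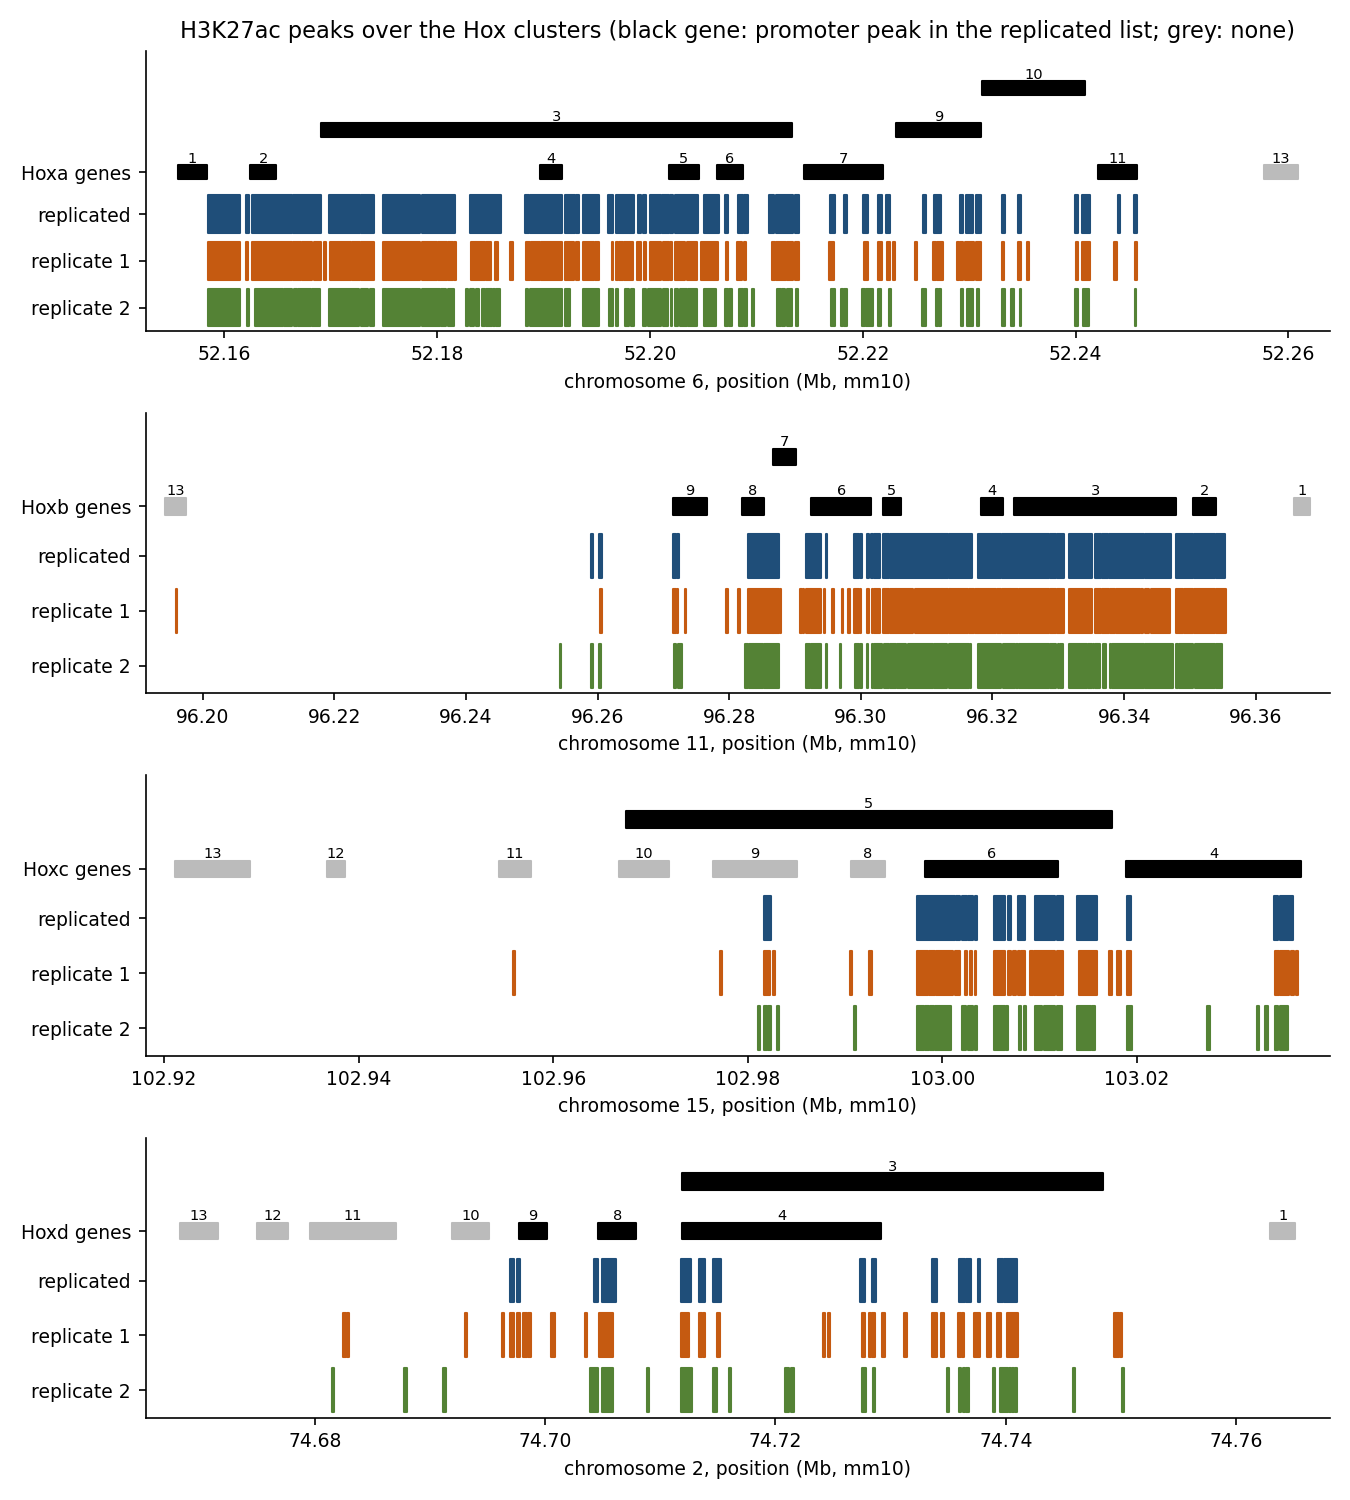
Peaks over the Hox clusters, by position in Mb (mm10), in the replicated list and in each replicate. Gene bars carry the paralogue number, with overlapping or adjacent genes on separate levels, and are black where the gene had a replicated promoter peak and grey where it had none; replicated peaks cover 45.2% of Hoxa, 33.8% of Hoxb, 13.2% of Hoxc and 8.53% of Hoxd, and within Hoxc they cover 66.3% of Hoxc6.

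Neighbouring peaks were stitched into 20592 domains, of which 8174 held a single peak. The domain with most covered bases lay on chromosome 7 from 142429801 to 142579176, where 55 peaks covered 79933 bp over Syt8, the troponin genes Tnni2 and Tnnt3, Lsp1, Mrpl23 and the imprinted non-coding gene H19. Replicate 1 covered 74760 bp and replicate 2 71221 bp of the same interval. It held first place in none of the alternatives: it ranked 2 by enrichment times width and in replicate 1's own list, 3 in replicate 2's, 4 with a stitching gap of 25 kb and 17 with one of 5 kb. The Hoxb cluster ranked next with 58827 bp and the Hoxa cluster ranked 9 with 47590 bp. The domain that ranked 5, on chromosome 18 from 61609297 to 61730860, covered 50753 bp around Il17b, Pcyox1l and Grpel2 and also held Mir143, Mir145a and Carmn, non-coding genes of smooth muscle. The other leading domains lay over Rbpms (57800 bp), Cstad (53241 bp), Zmiz1 (50679 bp), an interval within Gse1 (49293 bp), Myh9 and Txn2 (48281 bp), and Actn4, Eif3k and Map4k1 (46612 bp).

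The 206 domains with most covered bases held 11.2% of all covered bases and the TSSs of 435 protein-coding genes. These included 10 of the 25 genes of epithelial structure, Cdh1, Cldn3, Cldn4, Cldn7, Epcam, Ezr, Krt8, Krt18, Krt19 and Lgals4. They also included 5 epithelial transcription factor genes, Cdx1, Cdx2, Elf3, Gata4 and Gata5, 16 Hox genes, and the clustered apolipoprotein genes Apoa1, Apoa4 and Apoc3. Of the lists for other organs and the germ line, heart and skeletal muscle (Tnnt3) and lung and kidney (Ager) each had 1 gene in them, and liver, pancreas, stomach, brain and germ line had none. No smooth muscle, immune, erythroid, enteroendocrine, enteric neuron and glia, or Cajal and mesothelium gene had its TSS in them. These counts have no test. With a stitching gap of 25 kb, 2 of the leading 10 domains stayed among the leading 10, with a gap of 5 kb 5 did, and ranked by enrichment times width 4 did.

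Distal peaks were searched for the binding sequences of transcription factors that act in the gut. The HNF4 motif was present in 7.03% of 41931 distal peaks, 1.49 times its share in windows of the same GC content (lowest to highest of 20 draws 1.42 to 1.58). The FOX motif was at 1.48 times (1.40 to 1.52), the AP-1 motif at 1.38 (1.34 to 1.42), the CAGCTG E-box at 1.26 (1.25 to 1.28), the CTCF core at 1.23 (1.08 to 1.38) and the GATA motif at 1.18 (1.166 to 1.197). Smaller ratios were found for TEAD (1.11), the CArG box bound by serum response factor (1.10), CDX (1.09) and SOX (1.08), and the CATCTG E-box bound by TWIST and HAND factors lay below its matched windows at 0.961 (0.951 to 0.975). HNF4 and the CTCF core were more frequent than all 20 of their column-permuted strings, HNF4 narrowly (7.03% against at most 6.93%). For the other 9 motifs between 3 and 17 of the 20 strings were as frequent, with 11 for SOX and 17 for CArG. The CTCF core was also in 0.427% of the GC-matched windows outside peaks, above its most frequent permuted string in the peaks (0.246%). For this motif the permuted strings therefore do not set the peaks apart from other sequence. With a window of 200 bp the ratios fell to 1.30 for HNF4, 1.27 for FOX, 1.16 for AP-1, 1.12 for GATA and 1.02 for CDX. TEAD fell to 1.01 (0.976 to 1.05) and no longer lay above all draws, while SOX rose to 1.10. The CArG ratio turned to 0.969 and the CTCF core ratio to 0.559.

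Distal peaks near epithelial genes held CDX motifs in 29.9% of 586 peaks, against 21.3% of 328 peaks near mesenchymal and smooth muscle genes, an odds ratio of 1.57 (adjusted exact p = 0.0563 over 11 motifs, Fisher's exact test). The CATCTG E-box was in 28.8% against 35.7% (adjusted exact p = 0.205), and HNF4 motifs were in 6.66% against 5.79% (adjusted exact p = 0.781), a direction that turned in replicate 1's own list and with smaller windows. No motif passed the threshold. Many of these peaks lie near the same gene and are not independent, so the p values can be too small, also those from the replicates' own lists. In replicate 1's own list the CDX difference passed it (odds ratio 1.44, adjusted exact p = 0.0330), and in replicate 2's own list the CArG difference did (odds ratio 0.402, adjusted exact p = 0.0292); over all alternatives the adjusted p ranged from 0.0330 to 0.781 for CDX and from 0.0292 to 1 for CArG, whose odds ratio lay on both sides of 1.

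**Figure D3:**
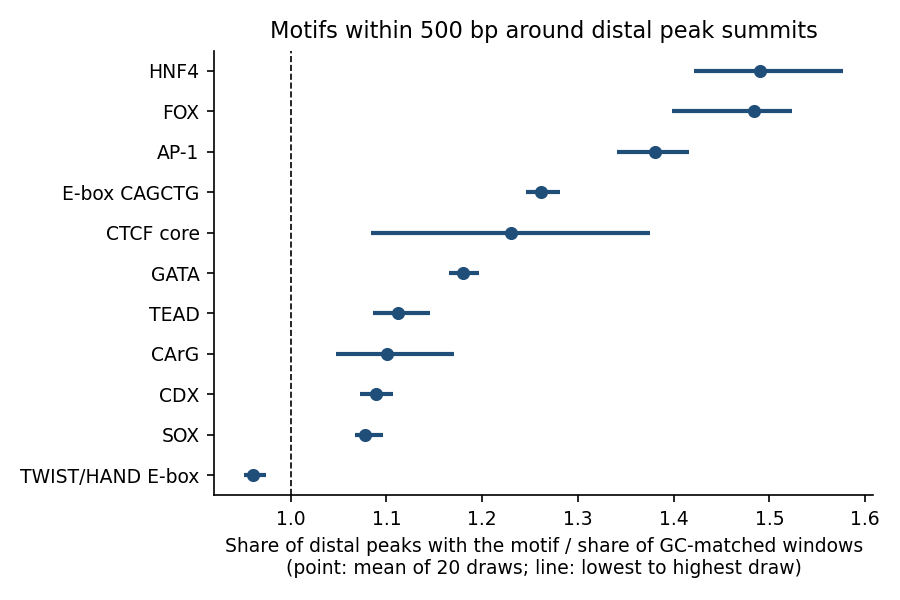
Ratio of the share of distal peaks with a motif to its share in GC-matched windows of the same chromosome, for a window of 500 bp around the peak summit. Points are means of 20 draws and lines run from the lowest to the highest draw; HNF4 is at 1.49 and FOX at 1.48, with overlapping draws, and the TWIST/HAND E-box alone lies below the dashed line at 1.

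Promoters held 35.3% of the replicated peaks (exact 95% interval 34.9% to 35.7%), against 8.41% after shuffling within chromosomes. Introns held 38.8% (39.3% shuffled), exons 3.53% (3.16%) and intergenic sequence 22.3% (49.1%). Promoter peaks were wider than distal peaks, with medians of 675 bp and 452 bp, and their median enrichment was 6.18 against 4.08. The 10 strongest distal peaks were intergenic except for 1 in an intron of Arid1b (34.4), and the genes with the nearest TSS to the others were Zfp869 (41.6), Ctdsp1 (39.2), Ccnl1 (37.5), Tomm20 (36.9), Nes (35.8), Ski (35.3), Mgme1 (34.3), Tpt1 (33.2) and H3f3a (32.8). The distance to that TSS was 119007 bp for Tomm20, 105067 bp for Mgme1 and 195738 bp for Arid1b, and between 4389 bp and 36025 bp for the other peaks. The peak with the highest enrichment lay 5999 bp from the TSS of Zfp869, on chromosome 8 from 69716272 to 69716968. The intervals cover counting of peaks only.

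The replicates shared more of their strong than of their weak peaks. Of replicate 1's peaks 60.6% overlapped a replicate 2 peak by at least 1 bp (shuffled 3.16%), and of replicate 2's 72.1% overlapped a replicate 1 peak (shuffled 3.64%). The 20000 peaks with the highest enrichment were found in the other replicate's full list at 99.4% for replicate 1 and 99.6% for replicate 2. Of the peaks with an enrichment of at least 4, 88.5% of replicate 1's and 90.6% of replicate 2's were found there, which leaves 5071 and 4252 without a partner. In the lowest decile of enrichment the overlap was 31.8% for replicate 1 and 50.2% for replicate 2. The 40768 peaks of replicate 1 without a partner had a median enrichment of 3.13 and a width of 211 bp, against 4.56 and 427 bp for those with a partner; in replicate 2 these values were 3.28 and 205 bp for 25320 peaks, against 4.55 and 388 bp. The Jaccard index of covered bases was 0.533 (shuffled 0.00997), with 31.7 Mb in common. Across 62803 shared peaks, which are not independent replicates, the enrichments had a Spearman rho of 0.668 and a Pearson r of 0.763 on the log2 scale.

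**Figure D4:**
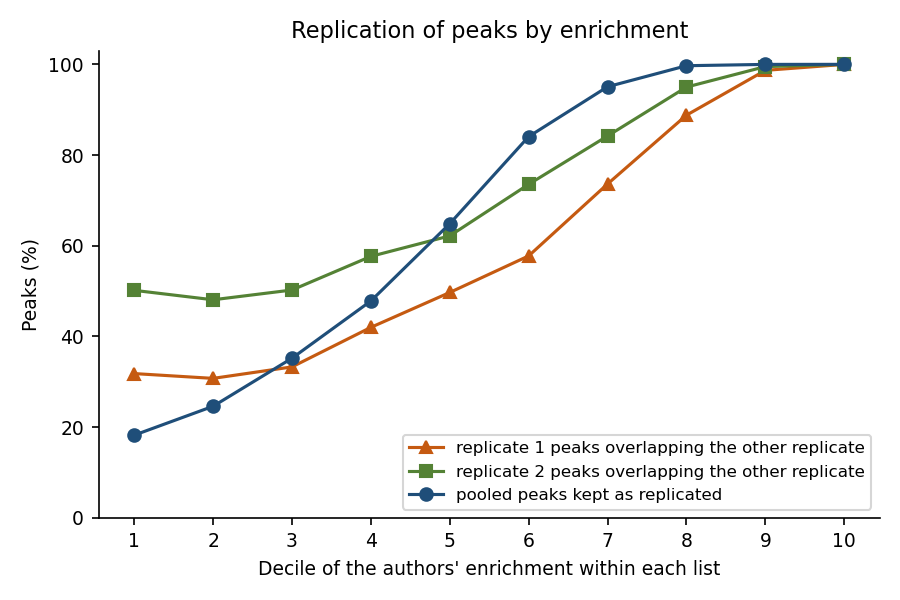
Percent of peaks overlapping the other replicate (triangles, replicate 1; squares, replicate 2) and percent of pooled peaks kept as replicated (circles), by decile of the authors' enrichment within each list. All 3 series lie at or near 100% in the highest decile; in the lowest they are at 31.8%, 50.2% and 18.2%.

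The replicated list held 66.95% of the pooled peaks, each at identical coordinates. Pooled peaks that overlapped both replicate lists were kept in 99.2% of 54969 cases, those overlapping replicate 1 alone in 29.7%, those overlapping replicate 2 alone in 28.9%, and those overlapping neither in 6.37% of 8538. Kept peaks had a median enrichment of 4.47 and a width of 513 bp, and removed peaks 2.85 and 215 bp. With an enrichment of at least 4, 98.5% of the pooled peaks were kept.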

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

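A few peaks lay on contigs outside chromosomes 1 to 19, X and Y, which no comparison used: 8 in replicate 1, 10 in replicate 2, 9 in the pooled list and 6 in the replicated list. They were singled out as a signal above 0 in sequence that was otherwise left out. No control sample was analysed here to set them against, and no explanation was tested.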

How the results depend on the processing

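Most comparisons of a gene list with an alternative stayed on their side of the threshold and did not cross their background, although some distal medians met it. For the promoter share 199 of 225 stayed, 18 lost the call, 4 gained it and 4 turned; for covered bases 167 of 175 stayed, 5 lost the call and 3 turned; for distal peaks 156 of 175 stayed, 14 lost the call, 3 gained it and 2 turned. Among these turns, the immune list alone began from a call: its share of 31.8% lay above random lists matched on promoter CpG (adjusted permutation p = 0.701; over all alternatives 2.14e-05 to 0.701). Turned without a call were the promoter shares of endothelium with an enrichment of at least 4 (40%), of Hox genes against CpG-matched lists (64.1%) and of enteric neurons and glia in replicate 1's own list (56% to 60% without a replicate). So were the covered bases of endothelium with a 25 kb window (1080.5), with an enrichment of at least 4 (173.5) and in replicate 1's own list (645 to 737.5 without a replicate), and the distal peaks of liver and germ line genes in that list (2 to 2.5 without a replicate, for both). Lists called lower for the promoter share numbered 10; they fell to 6 with the pooled list and to 4 with CpG-matched random lists. In an alternative chosen after seeing the data, random runs of neighbouring genes, the Hox list lost its call for covered bases (3612, adjusted permutation p = 0.115) and kept that for distal peaks (8, 0.0160). The cause was not tested except where named.

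Overlap between replicates depended on what counts as shared. For replicates 1 and 2 it was 52.4% and 64.5% when at least 50% of the peak had to be covered, and 41.1% and 47.0% with a reciprocal overlap of 50%. It was 72.5% and 74.2% with an enrichment of at least 4 in both lists (Jaccard index 0.6004), 74.2% and 81.4% with a −log10 q of at least 5 (0.628), 64.7% and 68.4% with equal numbers of peaks (0.541), and 78.1% and 80.7% for the leading 20000 of each (0.625). Correlations of enrichment rose to 0.773 (Spearman) and 0.841 (Pearson) with reciprocal overlap and to 0.721 and 0.795 with an enrichment of at least 4. Pooled peaks with an enrichment of at least 4 were kept in 98.5% of cases.

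The share of peaks at promoters was 30.99% with a 500 bp window and 44.9% with 2.5 kb, which follows from the window's size. It was 44.8% with an enrichment of at least 4, 32.6% with the summit inside the window, 29.5% in the pooled list and 29.4% to 31.5% with a replicate left out. Of the leading 10 domains, 5 were kept with a 5 kb gap, 2 with 25 kb, 4 when ranked by enrichment times width, and 6 to 7 without a replicate. Another domain took first place in each of these: 1 at Zfp36l1 with a 25 kb gap (125606 bp) and in replicate 1's own list, 1 at Cstad when ranked by enrichment times width (53241 bp), and the Hoxb cluster with a 5 kb gap and in replicate 2's own list; the bases covered in the Hoxd cluster fell to 3965 with an enrichment of at least 4.

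With a 200 bp window the motif ratios of CArG (0.969) and the CTCF core (0.559) turned below 1. Without a replicate the odds ratio of CArG was 0.402 to 1.10 and that of CDX 1.40 to 1.44, with 1 value past the threshold for each (adjusted exact p = 0.0292 without replicate 1 for CArG and 0.0330 without replicate 2 for CDX). Odds ratios without a call that turned were those of HNF4 with a 20 kb window (0.853), with a 200 bp window (0.979) and without a replicate (0.761 to 1.07), FOX with a 100 kb (0.984) and a 200 bp window (0.778), the CAGCTG E-box with a 100 kb window (1.01), GATA (0.945) and CArG (1.69) with a 200 bp window, and TEAD without a replicate (0.721 to 1.03). The CTCF core gave no odds ratio with a 20 kb window to genes or a 200 bp motif window, where no peak near mesenchymal and muscle genes held it. No paired analysis was possible because there is only 1 group. Depth is unknown, so peaks missing from a list may be below its threshold; in the lowest enrichment decile most of replicate 1's peaks had no partner, and the overlap changed to the 72.5% given above once weak peaks were set aside.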

Other observations

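The counts of gene families and gene types, the tests of skeletal muscle, of a larger epithelial share and of the calling threshold, the counting of each peak once and the choice of the 3 patterns weighed here came after the results they concern had been seen. The wording of the threshold test was also changed after its result, which moved that explanation from being met to undecided.

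Families used by most cells had promoter peaks at most members. Promoter peaks were present at 36 of 37 genes of NADH dehydrogenase subunits, 89.2% of the genes of cytosolic ribosomal proteins and 33 of 39 of the proteasome. Against 56.0% of all protein-coding genes, 22 of 44 collagen genes and 16 of 26 integrin genes had one. The shares were lower for claudins (10 of 33, exact 95% interval 15.6% to 48.7%), keratins (8 of 49, 7.32% to 29.7%) and Wnt ligands (4 of 19, 6.05% to 45.6%). Solute carriers, the transporters of nutrients and ions, had them at 211 of 342 genes, and cytochromes P450 at 22 of 99. Sensory and neuronal families were nearly bare, with 0 of 1135 olfactory receptor genes, 2 of 329 vomeronasal receptor genes and 2 of 57 clustered protocadherin genes. None of the 22 alpha-defensin genes, which Paneth cells express, had a promoter peak in the replicated list or in either replicate's own list.

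Outside protein-coding genes, a peak lay within 1 kb of a TSS for 35.05% of 2959 antisense genes, 16.5% of 5854 lincRNA genes, 16.4% of 2202 microRNA genes and 1.93% of 9940 processed pseudogenes. No count was made away from protein-coding TSSs, so these shares can include peaks of nearby protein-coding promoters. The domain on chromosome 18 that held Mir143, Mir145a and Carmn covered 48376 bp in replicate 1 and 43509 bp in replicate 2. Pancreas genes had a median of 4 distal peaks within 50 kb against 1 in random lists (adjusted permutation p = 0.0554); the adjusted p was 0.0111 in replicate 1's list and 0.0455 in replicate 2's, and over all alternatives it ranged from 0.0111 to 1.

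Genes on the X chromosome had promoter peaks at 32.5% of 948 genes, against 57.6% of autosomal genes. Fewer CpG-rich promoters account for only part of this, since autosomal lists matched on promoter CpG had a mean of 48.2% (95% of lists 45.5% to 50.9%). Without multi-copy families and predicted genes the X share was 47.4% (exact 95% interval 43.2% to 51.7%) against 69.8%, so these too leave a gap, and with both corrections the matched autosomal mean was 61.2% (57.7% to 64.8%). The median enrichment of X promoters with a peak was 7.55, against 9.13 in matched autosomal genes (8.26 to 10.008), so X promoters may miss the calling threshold more often. The pools held both sexes, and the design has no second group, so no biological explanation was tested.

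Among peaks without a partner in the other replicate, pairs of an enterocyte gene and a peak within 50 kb numbered 108 in replicate 2 and 93 in replicate 1, a ratio of 1.87 when scaled to all such peaks (95% of matched random lists 0.666 to 1.49; adjusted permutation p = 0.049995 over 25 lists, at the threshold), and the scaled number was higher in replicate 2 at 20 of the 30 genes. With each peak counted once, since neighbouring genes share peaks, there were 93 and 83 peaks, the ratio was 1.80 and the call ended (adjusted permutation p = 0.105), so chance stays open. A larger share of epithelium in replicate 2 would raise other epithelial genes too, but the ratio over pairs was 1.05 for transcription factors and structure and 1.08 for the 109 genes of all other epithelial lists (random lists 0.830 to 1.25), although enteroendocrine genes alone had 1.65 (adjusted permutation p = 0.480). The enterocyte ratio exceeded both (permutation p = 0.019998 for each, corrected for the choice of this list among 25 and of the direction). With each peak counted once these permutation p values were 0.049995 and 0.0350. If the excess is more than chance, this argues, weakly, against a larger share of epithelium as the whole cause. Only unshared peaks were counted, so peaks that both replicates share near these genes could not show such a share. Weak peaks near the calling threshold stay open, since with an enrichment of at least 4 the ratio was 2.84 over pairs and 2.57 over peaks, within the wide 0.298 to 2.98 of random lists, and no biological explanation was tested.

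The domain over the troponin genes and H19 on chromosome 7, which came first in covered bases with the main settings but under none of the alternatives, could come from skeletal muscle carried along with the intestine. Of the 8 other skeletal muscle genes of the fixed list, only 1, Mylpf, had a promoter peak. That share decides little, since the lower call of the heart and skeletal muscle list ended against lists matched on promoter CpG. The abundant muscle genes Acta1 and Ckm had no promoter peak in any list, which argues, weakly, against that source. The peak at Mylpf goes the other way. Tnnt3, inside the domain, had a promoter peak in replicate 1 alone (3.35). Repeats covered 11.3% of the bases of the domain's peaks, close to the median of 11.9% in random sets of 55 peaks (95% of sets 9.16% to 15.1%), which leaves repeated sequence open. No biological explanation was tested.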
